A study of Mus musculus with 8 samples.

How the data were processed

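Total RNA was measured from choroid plexus of the fourth ventricle of mouse embryos at embryonic day 13, with 4 arrays labelled as Otx2 knockout and 4 labelled as wildtype. Each array held 1 biological replicate per the labels. The labels give a mixed strain background, state that the sex of the embryos was not determined, and place knockouts and wildtypes in the same litters. They do not say how many embryos went into a sample. RNA was extracted with a column kit for small amounts that included a DNase step, amplified and labelled with biotin, per the labels' protocols.

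The deposited values are log2 expression levels per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, brings the probe distributions of all arrays together and summarises the probes of a set. The RMA software, its version and any array filter are not given in the sources used here. Because RMA equalises the distributions, a change in the total RNA content of a cell cannot be seen in these values, and the brightest and dimmest probe sets have compressed differences. Scanner images and detection calls are not analysed here, so a low level cannot be separated from background, and no sequencing depth applies. The number of arrays limits the precision. Array medians lay between 5.85 and 5.90 log2 units, and no 2 of the 8 arrays held identical values.

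Of 45101 probe sets, 64 were controls, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none listed. Symbols were compared through their gene identifiers with the mouse reference gene table (assembly GRCm38.p6, used for names only). A total of 34754 probe sets had their identifier in that table, and 0 symbols needed an update. Only probe sets with 1 gene were named. The brightest probe set, by its mean over all 8 arrays, stood for each of 18193 genes, of which 9010 had several. No build was named for the array, so no coordinates are given.

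Knockout-labelled and wildtype arrays were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term, no filter on dim probe sets). Calls were made at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Every adjusted p of a gene below comes from this limma test. Fold changes are knockout-labelled minus wildtype, and values are means ± SD over 4 arrays. Single quantities were compared with exact permutation tests over the 70 assignments of 4 against 4 arrays, two-sided, for which 0.0286 is the smallest p. They form a family of 12. These assignments ignore the pairing of same-numbered arrays described below. Exchange only within the 4 pairs, added after seeing the data, has 16 assignments and a smallest two-sided p of 0.125, so no single quantity can pass 0.05 in it.

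Before the data were examined, 27 gene lists were written for the tissue, its neighbouring cell types and signalling pathways, holding 619 entries, of which 577 matched a measured gene. The other entries are not analysed here. The list of sex-linked transcripts served only to describe the arrays. The other 26 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists. Camera with an estimated correlation and fry, a test within each list, were run beside it. Members past the gene test were counted after adjustment over all genes and again adjusted over the list alone.

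The genes named were chosen by a rule fixed in advance. It took Otx2, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, leaving out clone or locus names and sex-linked transcripts. It also took up to 3 called members of each list with the smallest p, or the member with the smallest p where none passed. Other list members named in the text were chosen after their values were seen.

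Replicate numbers were shared between the groups. The deviations of same-numbered arrays from their group means correlated across genes at 0.131, 0.232, 0.160 and 0.223, each above the 0.1 set as the limit for pairing, while other pairs ranged from -0.296 to 0.294. The numbers were therefore treated as pairing the arrays in checks beside the main fit, which has no term for them. This pairing rests on the values only, since no label says that a number marks a litter. Of the 8 arrays, 5 correlated best with their own number. A fit with the replicate number as a block was compared with the unblocked one.

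Further alternatives were array weights, a trended robust variance prior, other ways to choose probe sets, a filter on dim genes, other normalizations, other thresholds, Welch's test, a sex covariate and leaving out each array. Covariates for the neuron list and for the difference between beta-actin control probe sets were added after seeing the data. The procedure was tested on simulated data with 18193 genes, of which 200 were changed. It recovered 52.2% of changes of 0.5 log2 units, 97.0% of changes of 1 and 98.5% of changes of 2, with 12 false calls among 177. The simulated noise was independent between genes and arrays, so these rates do not cover correlated genes, array effects or pairing. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 in Python 3.11.15.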

Results

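The series measured gene expression in the choroid plexus of the fourth ventricle, the secretory epithelium and its vascular stroma that make cerebrospinal fluid, at embryonic day 13 in the mouse. It asked how the tissue differs in embryos labelled as knockouts of Otx2, a homeodomain transcription factor of the anterior brain and the choroid plexus. There were 4 arrays labelled Otx2 knockout and 4 labelled wildtype, each a separate biological replicate per the labels. Array medians ranged from 5.85 to 5.90 log2 units.

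Otx2 itself did not fall. Its only probe set read 12.44 ± 0.04 log2 units in the arrays labelled knockout and 11.97 ± 0.09 in the wildtype arrays (SD, n = 4 each). The log2 fold change was 0.47 with an SE of 0.06 (limma, adjusted p = 0.000648), and all 4 knockout-labelled arrays lay above all 4 wildtype arrays (exact permutation p = 0.0286, adjusted p = 0.0571 in the family of 12, and p = 0.125 with exchange only within same-numbered pairs, the smallest that gives). The position of the probes relative to the deleted part of the gene is not given in the sources used here. If they lie outside the deleted part, the probe set checks nothing about the labels. Each direction below rests on the labels alone, so the arrays are called knockout-labelled throughout.

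The 2 groups of arrays stood apart. The first principal component of the 5000 most variable genes held 59.4% of their variance and separated all knockout-labelled from all wildtype arrays. The second held 15.9% and set knockout-labelled replicate 2 apart from the others of its group. Correlations across genes, which are not independent replicates, were 0.990 to 0.996 within the knockout-labelled group, 0.994 to 0.997 within the wildtype group and 0.984 to 0.989 between groups. The mean correlation within groups was higher than between groups by 0.00788.

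Between the groups, 3557 of 18193 genes passed the test (19.6%), 1426 higher and 2131 lower in the knockout-labelled arrays. The number higher was 905 without wildtype replicate 3 (1757 lower), and in the fits without 1 array it reached 1845, without knockout-labelled replicate 2. At least a fold change of 2 was reached by 327 of them, 116 higher and 211 lower. In 4429 genes (24.3%) the groups did not overlap, where chance gives 2.86%. Of 2050 called genes with several probe sets, 1003 had another probe set past the threshold in the same direction and 13 had one in the opposite direction.

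The largest rise was that of Calb2, the calcium-binding protein calretinin, from 6.77 ± 0.26 to 10.61 ± 0.08 log2 units, which is 14.3-fold (SE 0.12 log2, adjusted p = 2.79e-07). Gria1, an AMPA glutamate receptor subunit, rose from 4.63 ± 0.44 to 7.95 ± 0.61, or 9.96-fold (adjusted p = 8.34e-05). Dkk2, a secreted modulator of Wnt signalling, rose from 8.33 ± 0.05 to 11.11 ± 0.10, or 6.86-fold (adjusted p = 9.83e-08). Fmod, the collagen-binding proteoglycan fibromodulin, rose 4.78-fold to 11.22 ± 0.26. Gcnt1, a glycosyltransferase, rose 7.15-fold and the secreted protein gene C1qtnf3 rose 7.78-fold, the latter with a wide wildtype spread (5.82 ± 1.30). The log2 fold change of C1qtnf3 was 2.96 over all arrays and ranged from 2.55 to 3.56 in the fits without 1 array. Tmem200c rose 6.84-fold and Spock3, a testican proteoglycan, rose 4.85-fold. Other, dimmer probe sets of Tmem200c (log2 fold changes of 0.02 and -0.14) and of Spock3 (-0.06) did not pass, and a second one of Gcnt1 rose by 0.72.

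The largest fall was that of Pmch, the precursor of melanin-concentrating hormone, from 9.90 ± 0.59 to 6.82 ± 0.33 log2 units, or 8.48-fold (SE 0.27 log2, adjusted p = 6.52e-05). Myrip and Myo5b, which take part in vesicle transport along actin, were lower by 5.26-fold and 4.71-fold. Slc22a19, an organic anion transporter, was lower by 4.47-fold, from 8.75 ± 0.10 to 6.59 ± 0.32 (adjusted p = 1.66e-05). The serum esterase gene Pon1 was lower by 4.39-fold and the basigin-family gene Emb by 4.08-fold. A dim further probe set of Emb gave -0.02. Tmprss11a, a membrane serine protease, was lower by 4.58-fold, to a level of 3.24 ± 0.37 that lies under the lower quartile of all probe sets (4.33).

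**Figure D1:**
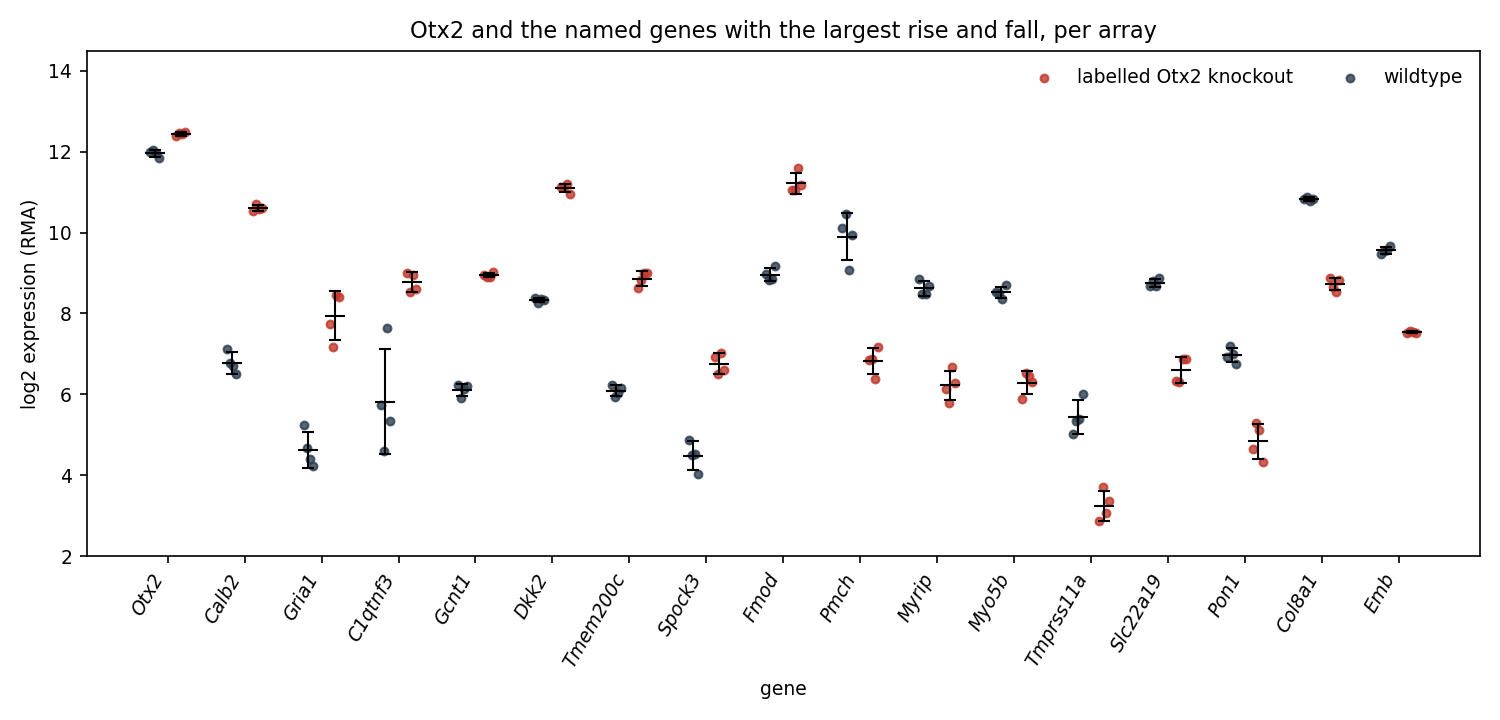
Log2 expression (RMA, vertical axis) of Otx2 and of the 16 genes with the largest rise and fall (horizontal axis), 1 point per array, with the mean and SD of 4 arrays labelled Otx2 knockout (red) and 4 wildtype arrays (dark blue). Otx2 was higher in the knockout-labelled arrays (12.44 against 11.97), and Calb2 rose from 6.77 to 10.61.

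Markers of the choroid plexus epithelium fell together. Of 27 measured members, 19 fell, 0 rose and 8 did not pass, with 19 falling when adjusted over the list alone, and the median log2 fold change was -0.81. Col8a1, a short-chain collagen, went from 10.84 ± 0.04 to 8.73 ± 0.16, a log2 fold change of -2.11 (SE 0.08, adjusted p = 1.38e-06). Tmem72 changed by -1.62 and Steap1 by -1.37. The folate receptor Folr1 changed by -1.12 and the potassium channel subunit Kcne2 by -0.83. Ttr, the thyroid hormone carrier transthyretin, was at 14.17 ± 0.03 against 14.21 ± 0.04 and did not pass (adjusted p = 0.647). It lies near the top of the range, where array differences are compressed. The list's adjusted p with camera was 1.72e-14, and the adjusted p was 0.156 with an estimated correlation.

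Ion and solute transporters fell as well, in 21 of 31 measured members, against 1 that rose (Clcn2, by 0.68), with a median of -0.81. Adjusted over the list alone, 23 fell and 2 rose. Slc4a10, a sodium bicarbonate transporter, went from 12.14 ± 0.04 to 10.51 ± 0.17, a log2 fold change of -1.63 (SE 0.08, adjusted p = 4.89e-06). The ascorbate transporter Slc23a2 changed by -1.48, the copper transporter Slc31a1 by -1.31 and the water channel Aqp1 by -1.01. Camera gave an adjusted p of 7.29e-14 for the list (adjusted p = 0.0979 with an estimated correlation).

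Genes of multiciliated cells showed the same direction. Of 34 measured members 29 fell and 0 rose, 29 and 1 when adjusted over the list alone, with a median of -0.82. Ccno, a regulator of centriole amplification, went from 8.87 ± 0.06 to 6.92 ± 0.36, a log2 fold change of -1.95 (adjusted p = 3.69e-05). The transcription factor Trp73 changed by -1.06 and the cilia gene Lrrc23 by -1.01. The list passed camera (adjusted p = 1.20e-20), against an adjusted p of 0.0979 with an estimated correlation. In all 3 of these lists the list mean of every knockout-labelled array was under that of every wildtype array. In the same arrays the means of the stroma and macrophage lists were higher by 0.54 and 0.62.

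Secreted and carrier proteins of the choroid plexus moved both ways, with 4 of 27 higher and 8 lower (6 and 9 adjusted over the list alone). Penk, the enkephalin precursor, changed by -1.77 and Clu, the chaperone clusterin, by -0.86. Cp, the copper-carrying ferroxidase ceruloplasmin, rose by 2.01. The median was -0.06 and the camera adjusted p 0.425 (adjusted p = 0.830 with an estimated correlation). The median was -0.12 without knockout-labelled replicate 3 (camera adjusted p = 0.115), -0.03 without knockout-labelled replicate 2 (0.748), -0.14 with the actin covariate (0.0924) and -0.02 with the neuron covariate (0.660). Among epithelial junction and polarity genes 10 of 26 fell and 4 rose (13 and 6 adjusted over the list alone). The tight junction gene Ocln changed by -1.23, the cadherin Cdh3 by -0.72 and the polarity gene Crb3 by -0.69. The 4 that rose included Cdh1, the cadherin of most epithelia, by 1.72 and Cldn11, a claudin, by 1.49. Their median was -0.21 and their mean 0.00, with a camera adjusted p of 0.164 (adjusted p = 0.656 with an estimated correlation). That mean depends on knockout-labelled replicate 3, whose list mean was 8.26 against 7.92, 7.90 and 7.94 in replicates 1, 2 and 4. The list passed with fry (adjusted p = 0.0436) and with camera over genes above the median level (adjusted p = 0.0358, median -0.38), while the mean of probe sets gave a median of -0.13 (camera adjusted p = 0.277).

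**Figure D2:**
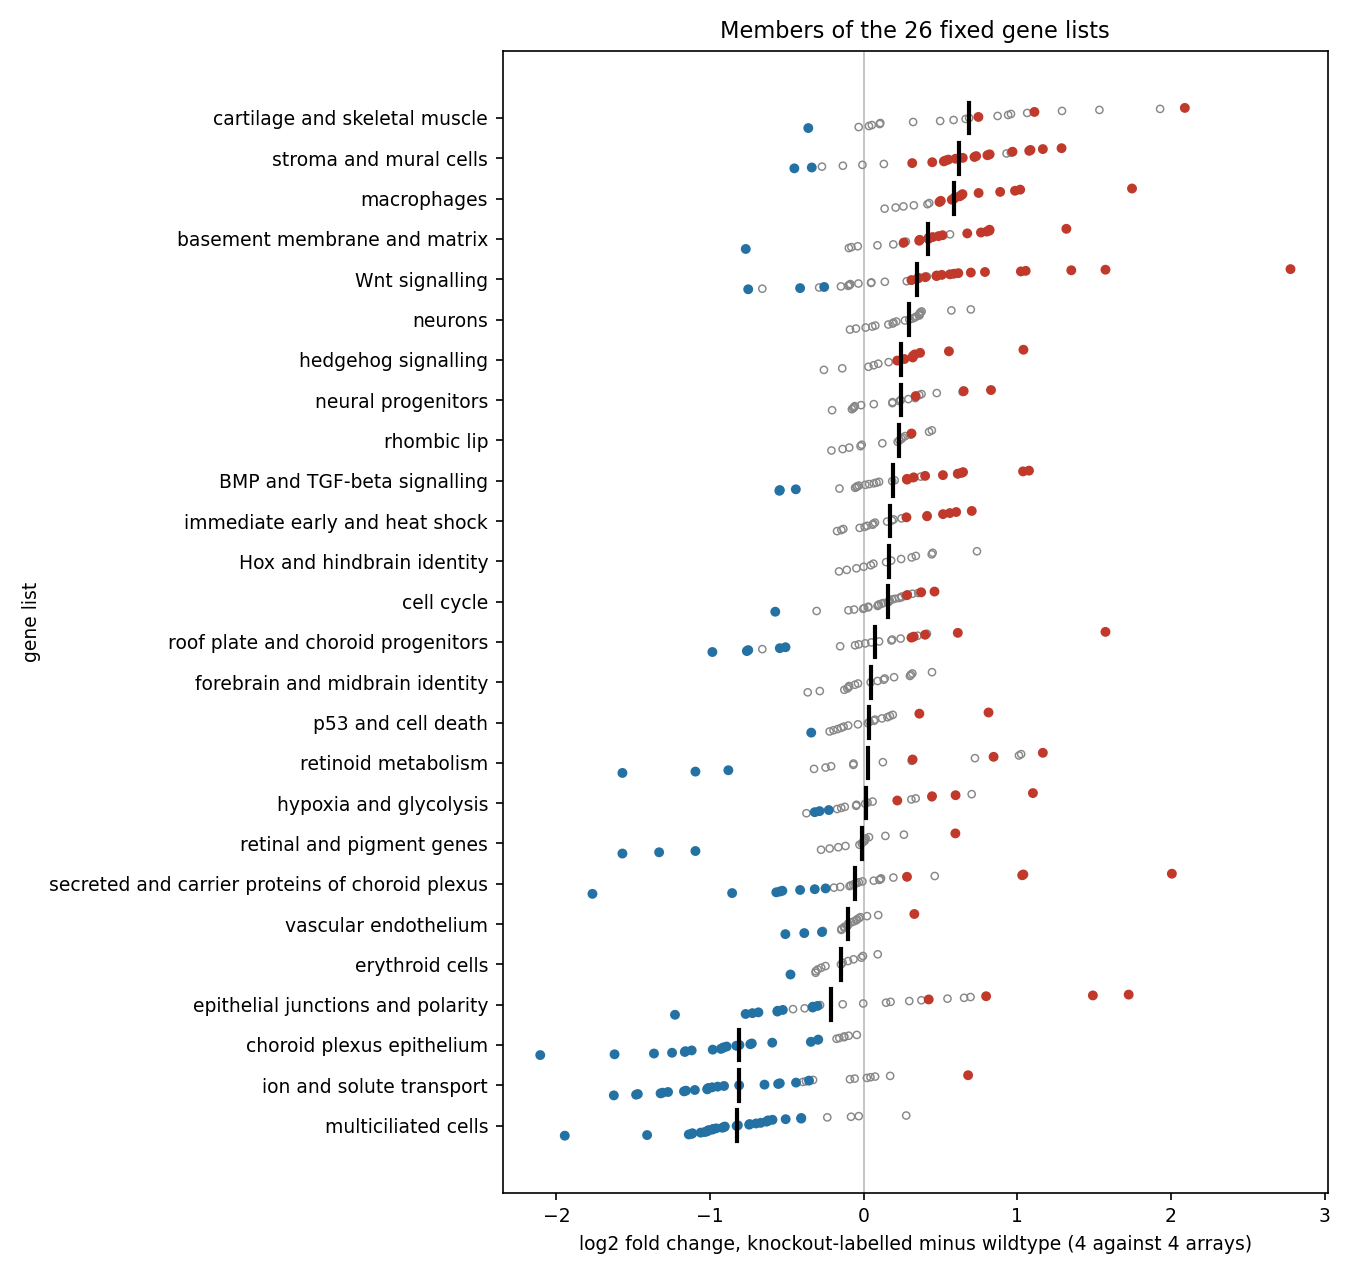
Log2 fold change of each measured member (horizontal axis, knockout-labelled minus wildtype, 4 against 4 arrays) of the 26 gene lists (vertical axis). Filled points passed the test, red higher and blue lower, open points did not, and black bars are list medians. The choroid plexus epithelium, transport and multiciliated lists lie lowest, with medians of -0.81, -0.81 and -0.82.

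Stromal, matrix and macrophage genes were higher in the knockout-labelled arrays. Of 24 stroma and mural cell genes 16 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.62. Lum, a matrix proteoglycan, rose by 0.53, the transcription factor Tbx18 by 0.60 and the collagen gene Col5a1 by 0.64. The 2 that fell, Abcc9 (-0.45) and Rgs5 (-0.34), are known as pericyte genes. As a set the list had an adjusted p of 2.66e-07 with camera and an adjusted p of 0.305 with an estimated correlation. Of 23 basement membrane and matrix genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.42. The collagen cross-linking enzyme Lox rose by 1.32 and the matrix protein Fbln1 by 0.82, while the protease Adamts1 changed by -0.77. Camera gave an adjusted p of 3.70e-07 for the list (adjusted p = 0.284 with an estimated correlation).

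Of 19 macrophage genes 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.59. Lyve1, a hyaluronan receptor, went from 8.27 ± 0.13 to 10.01 ± 0.54 (log2 fold change 1.75, adjusted p = 0.000594). F13a1, a transglutaminase, rose by 1.02 and Adgre1, the F4/80 antigen, by 0.89. The list passed camera (adjusted p = 1.77e-10), against an adjusted p of 0.284 with an estimated correlation.

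Endothelial and blood cell genes gave other values. Of 20 vascular endothelium genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.0901 (adjusted p = 0.656 with an estimated correlation). The camera adjusted p was 0.0193 without knockout-labelled replicate 1, 0.0177 without wildtype replicate 3, 0.0479 with the sex covariate and 0.0360 with the actin covariate. Without knockout-labelled replicate 2 the median was -0.04 (camera adjusted p = 0.375), and without wildtype replicate 2 it was -0.06 (camera adjusted p = 0.254). Plvap, a protein of endothelial diaphragms, changed by -0.51 and the sialomucin Emcn by -0.39. Cdh5, the cadherin of endothelial junctions, rose by 0.33 (adjusted p = 0.0454), but its adjusted p was 0.0827 with the replicate number as a block, and the call was lost in 7 of the 8 fits that left out 1 array, all but that without knockout-labelled replicate 2 (adjusted p up to 0.121). It was also lost with the mean of probe sets (adjusted p = 0.111), arrays centred on their medians (0.0706), the sex covariate (0.0781) and the actin covariate (0.119). Of 13 erythroid genes 1 fell, the heme synthesis enzyme Alas2 (-0.48), and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.0977 (adjusted p = 0.656 with an estimated correlation). Its camera adjusted p was 0.0399 and 0.0172 without knockout-labelled replicates 1 and 2, and 0.0381 without wildtype replicate 4, as well as 0.0258 with array weights and 0.0207 with the neuron covariate. The erythroid median was -0.25 without knockout-labelled replicate 2, -0.22 with array weights, -0.05 without knockout-labelled replicate 4 (camera adjusted p = 0.350) and -0.04 with the actin covariate (camera adjusted p = 0.630). With the replicate block or array weights 3 fell.

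**Figure D3:**
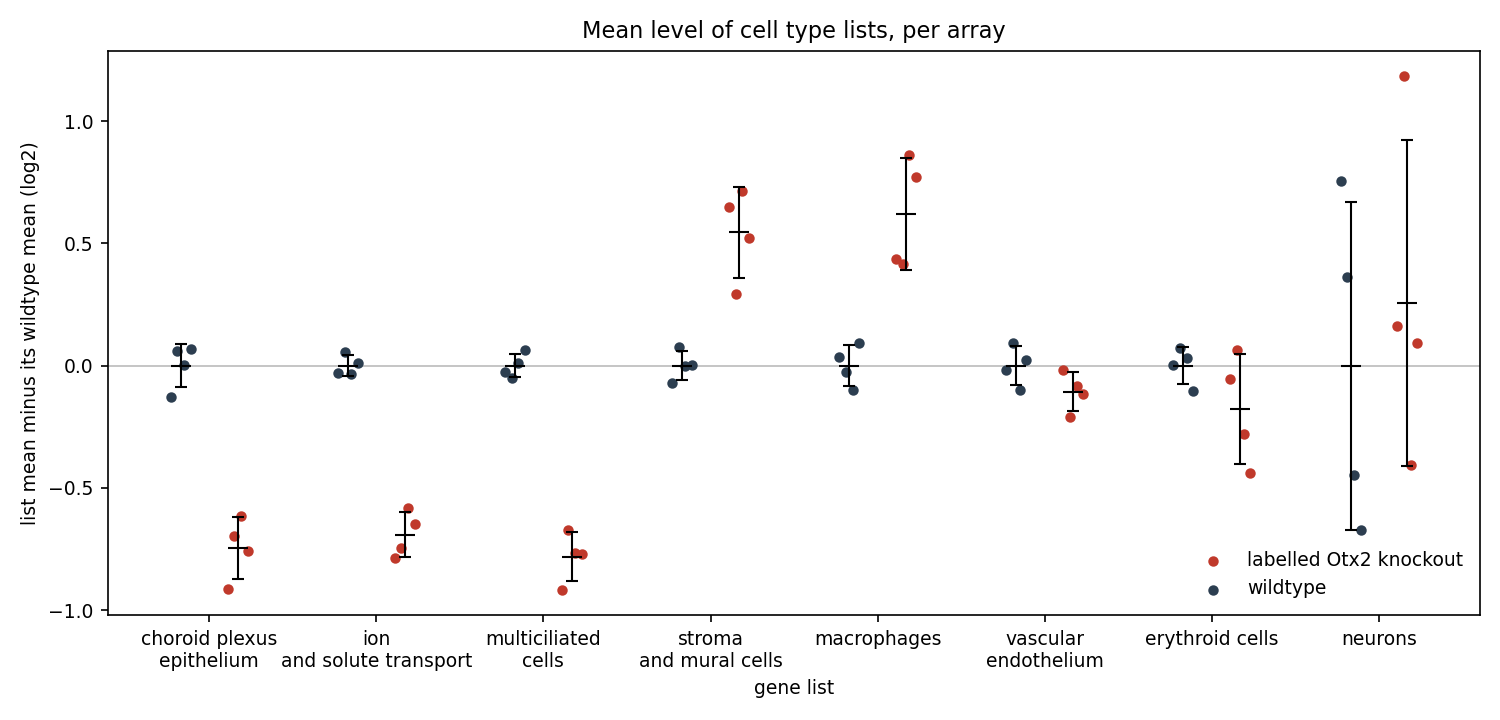
Mean log2 level of 8 gene lists (horizontal axis) per array, each minus the wildtype mean of its list (vertical axis, log2), for 4 arrays labelled Otx2 knockout (red) and 4 wildtype arrays (dark blue), with the mean and SD. Stroma and macrophage means were higher by 0.54 and 0.62 in the knockout-labelled arrays, and neuron means spread widely in both groups (SD 0.67 in each).

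Signalling genes rose more often than they fell. Of 36 Wnt pathway genes 17 rose and 3 fell (18 and 4 adjusted over the list alone), with a median of 0.34. Besides Dkk2, the secreted Wnt enhancer Rspo1 rose by 1.57, the receptor Fzd10 by 0.70, the ligand Wnt4 by 1.02 and the pathway target Axin2 by 0.56. The risers include both enhancers and inhibitors of the pathway, among the latter Wif1 (1.35) and Sfrp2 (1.05). A dim second probe set of Fzd10 gave 0.01. As a set the list had an adjusted p of 2.96e-05 with camera and an adjusted p of 0.156 with an estimated correlation. Of 28 BMP and TGF-beta genes 10 rose and 3 fell, the same counts as adjusted over the list alone, with a median of 0.19. The ligands Tgfb3, Tgfb2 and Gdf10 rose by 1.08, 1.04 and 0.61. Camera gave an adjusted p of 0.00339 for the list (adjusted p = 0.284 with an estimated correlation).

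Of 14 hedgehog genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.24. The co-receptors Gas1 and Cdon rose by 1.04 and 0.55 and the transcription factor Gli2 by 0.32. A dim further probe set of Gas1 gave 0.00. The list passed camera (adjusted p = 0.000399), against an adjusted p of 0.0979 with an estimated correlation. The number that rose was 4 without knockout-labelled replicate 3, without wildtype replicate 1 and without wildtype replicate 3, and 5 without knockout-labelled replicate 4, wildtype replicate 2 or wildtype replicate 4. With the mean of probe sets the median was 0.08. The number was 4 with the sex covariate and 5 with the mean of probe sets, arrays centred on their medians or the actin covariate.

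Roof plate and choroid progenitor genes, 17 of whose 22 measured members are also in other lists, split evenly, with 5 higher and 5 lower (7 and 6 adjusted over the list alone) and a median of 0.07. The roof plate factor Lmx1a changed by -0.76 and Foxj1, the regulator of motile cilia, by -0.99. The camera adjusted p was 0.450 (adjusted p = 0.823 with an estimated correlation). Without knockout-labelled replicate 4, 3 rose. The median was 0.12 without knockout-labelled replicate 2, 0.14 over genes above the median level and 0.05 with arrays centred on their medians. Of 15 rhombic lip genes only Wnt1 rose, by 0.31 (adjusted p = 0.0272), and 0 passed when adjusted over the list alone (limma, where Wnt1 was the member past the threshold over all genes). The Wnt1 call was lost in 6 of the 8 fits without 1 array (adjusted p up to 0.0732), with the sex covariate (0.0523) and with the actin covariate (0.0588), and held without knockout-labelled replicate 2 or wildtype replicate 3. The list had a median of 0.23 and a camera adjusted p of 0.164 (adjusted p = 0.656 with an estimated correlation), and of 0.0393 without wildtype replicate 1 and 0.0151 with the actin covariate. Its median was 0.35 and 0.37 in these fits, and 0.10 without wildtype replicate 3 (camera adjusted p = 0.421), 0.15 without wildtype replicate 2 and 0.14 with the mean of probe sets. With the replicate block 2 rose.

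Of 21 neural progenitor genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.24. The intermediate filament gene Nes rose by 0.65, Nkx6-1 by 0.83 and the glutamate transporter Slc1a3 by 0.34, and the last pair each lost the call in 4 of the 8 fits without 1 array. For Nkx6-1 these were the fits without knockout-labelled replicate 3 or 4 or wildtype replicate 1 or 2 (adjusted p up to 0.0782), and for Slc1a3 those without replicate 1 or 3 of the knockout-labelled group or 3 or 4 of the wildtype group (up to 0.0915). Slc1a3 also lost it without probe sets shared between transcripts or genes (adjusted p = 0.246), with the mean of probe sets (0.0526), the sex covariate (0.0590) and the actin covariate (0.0614), and Nkx6-1 with the actin covariate (0.0636). As a set the list had an adjusted p of 0.0245 with camera and an adjusted p of 0.651 with an estimated correlation. Its camera adjusted p was 0.167 without knockout-labelled replicate 2 and 0.114 without wildtype replicate 4, and 0.0639 with array weights. In these fits the median was 0.06, 0.10 and 0.11, and with the neuron covariate it was 0.07 (camera adjusted p = 0.0401). It was 0.38 without knockout-labelled replicate 3, 0.40 without wildtype replicate 1 and 0.41 with the actin covariate. The neuron list mean was highest in knockout-labelled replicate 2 (8.82). Without wildtype replicate 1 or with the actin covariate 6 members rose, and with the replicate block 5. Of 21 neuron genes 0 passed in either direction, also when adjusted over the list alone. Gap43, a growth cone protein, was higher by 0.57 with an adjusted p of 0.144. Without wildtype replicate 1 it passed (0.82, adjusted p = 0.00767), and without 1 array its log2 fold change ranged from 0.39 to 0.82 (adjusted p up to 0.320). The neuron list mean was 7.89 ± 0.67 in the knockout-labelled and 7.64 ± 0.67 in the wildtype arrays (exact permutation p = 0.600). The list's camera adjusted p was 0.164 (adjusted p = 0.823 with an estimated correlation), and it was 0.0113 without knockout-labelled replicate 3 and 0.00503 without wildtype replicate 1, and 2.26e-05 with the actin covariate. Its median was 0.30 over all arrays and 0.51, 0.54 and 0.84 in these fits, in that order. It was -0.05 without knockout-labelled replicate 2 (camera adjusted p = 0.999), -0.01 and 0.13 without wildtype replicates 4 and 3, and 0.04 with array weights. The median of -0.04 with the neuron covariate says nothing further. That covariate is the mean of this same list and takes out its shared difference by construction.

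Among 29 cell cycle genes, 3 were higher and 1 lower (2 and 1 adjusted over the list alone), with a median of 0.16. Cdk1, the mitotic kinase, changed by -0.58, while the replication helicase genes Mcm7 and Mcm5 rose by 0.46 and 0.37. Another 3 probe sets of Mcm7 did not pass, its call was lost with the mean of probe sets (adjusted p = 0.117) and without probe sets shared between transcripts or genes (0.240), and the Mcm5 call was lost without wildtype replicate 3 (adjusted p = 0.0507). The list's camera adjusted p was 0.0110 (adjusted p = 0.656 with an estimated correlation), and it was 0.0833 without knockout-labelled replicate 1 and 0.0856 without knockout-labelled replicate 4, with a median of 0.10 in each of these fits. The median was 0.23 without knockout-labelled replicate 3 and 0.08 with the mean of probe sets. The number that rose was 7 without knockout-labelled replicate 2, with the replicate block or with array weights, 6 with cyclic loess or over genes above the median level, 5 with a trended robust prior or quantile normalization, and 1 without wildtype replicate 3, with the mean of probe sets or without shared probe sets.

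Of 20 immediate early and heat shock genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.17. Jun rose by 0.70, the small heat shock gene Hspb1 by 0.52 and Ier3 by 0.41. The camera adjusted p was 0.0164 (adjusted p = 0.452 with an estimated correlation), and it was 0.0539 without knockout-labelled replicate 3, 0.0821 over genes above the median level and 0.0732 with the actin covariate. Ier3 lost its call without wildtype replicate 3 (adjusted p = 0.0501), and Hspb1 without wildtype replicate 2 or 3 (0.0515 and 0.0511) or with the actin covariate (0.0513). The number that rose was 3 without knockout-labelled replicate 1, without wildtype replicate 2 or with the actin covariate. Of 18 genes of p53 and cell death 2 rose and 1 fell (2 and 1 adjusted over the list alone). Bcl2l11, which promotes apoptosis, rose by 0.81 and Btg2 by 0.36, while Ccng1 changed by -0.34. Btg2 lost its call in 6 of the 8 fits without 1 array, all but those without knockout-labelled replicate 3 or wildtype replicate 2 (adjusted p up to 0.0932), and with the sex covariate (0.0619). The median was 0.03 and the camera adjusted p 0.691 (adjusted p = 0.823 with an estimated correlation). In the fits run the median ranged from -0.03 with the actin covariate to 0.04 without knockout-labelled replicate 1.

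Retinoid genes moved both ways, with 3 of 16 higher and 3 lower (3 and 3 adjusted over the list alone) and a median of 0.03. Rlbp1, a retinaldehyde carrier, changed by -1.57, the retinol-esterifying enzyme Lrat by -0.88, to a level of 3.94 ± 0.18, and the carrier Crabp2 rose by 0.85. The camera adjusted p was 0.990 (adjusted p = 0.994 with an estimated correlation). The median was -0.08 and 0.13 without knockout-labelled replicates 3 and 2, and 0.31 over genes above the median level. The number that rose was 1 without replicate 1 or 3 of either group. Of 17 retinal and pigment genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), among the latter Mitf, the pigment cell transcription factor, by -1.33 and the retinol dehydrogenase Rdh5 by -1.10. The median was -0.01 and the camera adjusted p 0.164 (adjusted p = 0.651 with an estimated correlation). Its camera adjusted p was 0.0378 without knockout-labelled replicate 2 and 0.0161 over genes above the median level, and fry gave 0.0150. The median was -0.09 without knockout-labelled replicate 2 and -0.0032 without wildtype replicate 2, and it was -1.21 over genes above the median level, where 2 members were left.

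Of 20 hypoxia and glycolysis genes 4 rose and 3 fell (7 and 4 adjusted over the list alone), with a median of 0.02. The peptide hormone gene Adm rose by 1.10, while Vegfa changed by -0.32 and Pgk1 by -0.29. The camera adjusted p was 0.489 (adjusted p = 0.656 with an estimated correlation), and the list passed with fry (adjusted p = 0.0352). In the fits run the median ranged from -0.05 over genes above the median level to 0.05 with the actin covariate. The number that rose was 2 without replicate 1 or 4 of the knockout-labelled group and without replicate 2 or 3 of the wildtype group. Of 21 cartilage and skeletal muscle genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.69. The cartilage genes Hapln1 and Col11a1 rose by 1.11 and 0.75, and Sox9 changed by -0.36. The list means of knockout-labelled replicates 1 and 2 were 7.15 and 7.25, those of replicates 3 and 4 were 6.31 and 5.91, and the wildtype arrays ranged from 5.80 to 6.10, so the groups overlapped. The Col11a1 call was lost with the actin covariate (adjusted p = 0.0575), and its other probe set did not pass (0.70, adjusted p = 0.0922). Camera gave an adjusted p of 0.00518 for the list (adjusted p = 0.615 with an estimated correlation). Over genes above the median level only, the camera adjusted p was 0.344. The number that rose was 5 without knockout-labelled replicate 2 or with array weights and 6 without knockout-labelled replicate 4, and it was 9 with the actin covariate.

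Among regional identity genes, 0 of 14 Hox and hindbrain genes and 0 of 17 forebrain and midbrain genes passed the unblocked limma test over all arrays, adjusted over all genes or adjusted over the list alone. Hoxa2 was higher by 0.44 (adjusted p = 0.191, and 0.0471 with the replicate number as a block). Six3 gave -0.36 (adjusted p = 0.0860), and it passed with the block (0.0396), array weights (0.0113), cyclic loess (0.0418), quantile normalization (0.0433) and without knockout-labelled replicate 2 (-0.50, adjusted p = 0.00360), with an adjusted p of up to 0.210 in the fits without 1 array. Its 2 other probe sets gave -0.09 and -0.10 and did not pass (adjusted p = 0.456 and 0.364). The camera adjusted p was 0.420 for the Hox list (adjusted p = 0.823 with an estimated correlation) and 0.00332 without wildtype replicate 1, where the median went from 0.16 to 0.56. The lowest and highest medians of the Hox list in the fits run were -0.04, without wildtype replicate 2, and that 0.56. For the forebrain list camera gave an adjusted p of 0.796 (adjusted p = 0.921 with an estimated correlation). Its median was 0.04, with -0.08 without knockout-labelled replicate 3 and 0.11 without knockout-labelled replicate 1. Over genes above the median level, where 1 member was left, the value was 0.30.

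In all, 13 of the 26 lists passed camera with the preset correlation, 10 higher and 3 lower. With an estimated correlation camera called 0, with 5 lists at an unadjusted p under 0.05, and fry called 12. Of the 13, fry did not call the neural progenitor, cell cycle, immediate early and cartilage lists (adjusted p = 0.170, 0.305, 0.0576 and 0.148). It called 3 lists that camera did not, those of epithelial junctions, hypoxia and retinal genes (adjusted p = 0.0436, 0.0352 and 0.0150). Of called genes named above, further probe sets that did not pass gave -0.32 for Myo5b, -0.31 for Slc23a2, 0.15 for Fbln1, 0.17 for Lox, 0.19 for Cdon, 0.05 for Mcm5, -0.26 for Lrat, -0.16 for Sox9, -0.18 for Vegfa, -0.24 for Pgk1 and -0.25 for Ccng1. For Slc1a3 they gave 0.34, 0.11 and 0.69, and for Cdh5 0.09 (limma over probe sets, adjusted p = 0.584). The control probe sets for ribosomal 18S RNA were lower in the knockout-labelled arrays, the 3' one at 12.10 ± 0.26 against 12.72 ± 0.09 (exact permutation p = 0.0286, adjusted p = 0.0571, and p = 0.125 within pairs). The difference between the 3' and 5' beta-actin controls was 0.315 ± 0.0744 against 0.260 ± 0.0340 (exact permutation p = 0.229).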

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

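Of the tests below, the comparisons of other cell types' lists and the meningeal list were chosen only after the result was seen. The actin and neuron covariates and the exchange within pairs were added after seeing the data.

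The first pattern is the fall of the choroid plexus epithelium, transport and multiciliated lists, in which 69 of 92 members fell. With the other cell types in fixed proportions to each other, a lower share of epithelial cells in the tissue would raise all their lists alike. Those proportions were not tested. The stroma list's median instead lay 0.723 log2 units above that of the endothelium list (permutation p = 5e-04 over members, which are not independent). A lower share in fixed proportions may thus not be the whole cause, while a lower share with a shift among the other cell types stays open. The trend in 3' over 5' beta-actin signal also left the pattern in place, since the median over the 92 members was -0.814 with the actin covariate and -0.815 without it, and 67 of the 69 still passed. Other differences in RNA quality stay open, because the 3', 5' and middle 18S controls were lower in every knockout-labelled array (by -0.62, -0.32 and -0.33, exact permutation p = 0.0286 and adjusted p = 0.0571 each, or 0.125 within pairs) and were not used as a covariate, and so do genotype as a hypothesis, labels that the Otx2 probe set does not check and a change within the cell types that rose.

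The second pattern is the rise of the stroma, matrix and macrophage lists. The median of their 66 members lay 0.631 above that of the endothelium and erythroid members. A lower epithelial share with the other cell types in fixed proportions may thus not be the whole cause. A lower share with a shift among those cell types stays open. The permutation p of 1e-04 over members, the smallest that 10000 permutations can give, measures spread over genes and not over arrays. The members are not independent, and the comparison was chosen after the result was seen. Against 1 divergent array, the median of the 66 members stayed at 0.491 or more in the fits without 1 array, with 0.527 over all arrays. Differences in RNA quality stay open here too, since the lower 18S controls of the same arrays were not used as a covariate. Meningeal cells in the dissected tissue could be a source. A meningeal list of 19 genes, 18 of them measured and 0 of them in the other lists, had a median of 0.201, above 99.99% of 10000 matched random lists but under the 0.3 set as its bound, with 6 members higher and 3 lower, and its array means overlapped between groups (exact permutation p = 0.229), so the lists leave this open. Its most abundant members in wildtype arrays, Ptgds (10.97), Bgn (10.53) and Thbd (9.97), changed by -0.92, 0.52 and 0.61, and 10 of the 18 lie above the median level of genes in wildtype arrays.

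The third pattern is the 8 genes with the largest rise, with a median log2 fold change of 2.81. Neural tissue carried along in the dissection would be a candidate source for Calb2 and Gria1, and S100b, Gad1, Calb1 and Reln, chosen after their values were seen, rose by 2.12, 2.04, 2.03 and 1.67 in the same arrays. With the neuron list mean as a covariate the median was 2.81 and 8 of 8 genes passed. The list mean overlapped between groups and did not pass (7.89 against 7.64, exact permutation p = 0.600), so this covariate could shift the median little. With the sex covariate the median was 2.84 and 8 of 8 passed. That covariate ran from -1.62 to 0.32 in the knockout-labelled and from -4.89 to 6.10 in the wildtype arrays, so it could shift the median little. Both fits took genes that had been chosen for groups that did not overlap. The outcome of both fits was thus close to fixed in advance, and neither tells whether neurons or sex had a part. Neural cells outside the list, other cell types and genotype were not tested for these 8 genes and stay open.

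Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many called genes as the real one, which was the real split itself with 3557, and the highest of the others gave 2. That share of 1 in 35 is under 0.05 and argues against chance for that count. It is also the smallest share that these 35 splits can give, and they ignore the pairing. Among the 8 splits that part all 4 same-numbered pairs, the real one included, no share under 0.05 can be reached, and the highest of the others there gave 0 genes (limma). For the lists, 8 of the 35 splits gave as many as the real 13, and the highest of the others gave 15. Each of the others with that many kept most arrays of each group together, so part of the difference between the groups stayed in it. Splits that mixed the groups evenly gave up to 12 lists. The splits can therefore not tell whether chance alone gives that many. Chance is not excluded for the number of lists called with the preset correlation. Among the splits that part all 4 pairs the highest other value was 13, also from a split that kept most of each group together.

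Single arrays lay far from the rest of their group in 10 of 220 groups of values tested, where chance gives about 1 in 20. Wildtype replicate 1 was lowest for Clu (11.83), Wnt1 (6.87) and the mean of the Wnt list (7.37). Wildtype replicate 3 was lowest for Rdh5 (8.06) and for the 3' control probe set of 18S RNA (12.58), and wildtype replicate 4 was highest for Emcn (10.04). Knockout-labelled replicate 1 was lowest for Foxj1 (9.56) and Bcl2l11 (9.79), replicate 4 was highest for Sox9 (9.39), and replicate 3 was highest for the mean of the epithelial junction list (8.26).

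Signals outside the gene comparison were also measured. The 3' control probe set of 18S RNA differed by -0.62 log2 units between knockout-labelled and wildtype arrays, with all 4 below all 4 (exact permutation p = 0.0286, adjusted p = 0.0571 in the family of 12, and p = 0.125 within same-numbered pairs, the smallest that their exchange gives). The difference between 3' and 5' beta-actin controls was higher by 0.0549 in the knockout-labelled arrays, which did not pass (exact permutation p = 0.229). Of 10092 probe sets without a single gene name, 365 passed the limma threshold, 179 higher and 186 lower.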

How the results depend on the processing

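The count of 3557 called genes became 1950 at an adjusted p under 0.01, 327 with a fold change of at least 2, 2163 with Welch's test per gene and 5407 when every probe set was counted on its own. The first pair follows from stricter thresholds and the last from counting probe sets, while the cause for Welch's test was not tested. Leaving out 1 array gave 2653 to 3934 genes, 12 to 16 lists, and 0.43 to 0.50 for the log2 fold change of Otx2. Otx2 stayed higher and past the threshold in every fit run, with adjusted p values from 1.89e-05 to 0.00446. Camera with an estimated correlation called 0 lists, with 5 at an unadjusted p under 0.05, where fry called 12. With the replicate block 3653 genes were called, 3206 of them among the 3557 and in the same direction, and 13 lists. The block ended the call of Cdh5 (adjusted p = 0.0827) and gave calls to Hoxa2 (0.0471) and Six3 (0.0396), and it changed no other call of a list or named gene. It raised the count of called cell cycle risers from 3 to 7, of progenitor risers from 3 to 5 and of erythroid fallers from 1 to 3. Centring arrays on their medians gave 32.7% higher calls against 40.1%. With the actin covariate, added after seeing the data, the neuron list passed (adjusted p = 2.26e-05). None of the called lists and called named genes changed direction in any alternative run. Low levels limit the folds of dim genes, and no detection call was used to separate them from background.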

Other observations

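The genes named next and the count of arrays with both Xist and Eif2s3y were chosen only after the values were seen.

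Several genes outside the rule for named genes also changed strongly in the knockout-labelled arrays. The gap junction genes Gjb2 and Gjb6 rose by 1.75 and 1.86 log2 units (limma, adjusted p = 5.73e-05 and 3.77e-05), the transcription factor Osr1 by 1.73 and the lipocalin Apod by 1.58. S100b rose by 2.12, Gad1 by 2.04, Calb1 by 2.03, Reln by 1.67 and Sncg by 1.37, genes picked singly and not tested as a set. The centriole gene Deup1 went from 10.07 ± 0.12 to 8.07 ± 0.35, or 3.99-fold lower. The protease inhibitor gene A2m changed by -1.93, the quinone reductase gene Nqo1 by -1.87, the potassium channel gene Kcnj3 by -1.80 and Crhbp, which binds corticotropin-releasing hormone, by -1.48.

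The sex-linked list had 4 measured members, 0 of which passed the limma test over all genes or adjusted over the list alone. Xist was at 11.62 ± 0.34 in the knockout-labelled and 9.94 ± 2.67 in the wildtype arrays (exact permutation p = 0.257). In 6 of the 8 arrays Xist, expressed from the inactive X chromosome, and the Y-linked Eif2s3y both lay more than 2 log2 units above their lowest arrays (6.06 and 3.10). In these 6 arrays the Y-linked minus Xist covariate lay between -1.62 and 1.45, against 6.10 and -4.89 in wildtype replicates 1 and 2. These values argue against RNA from a single embryo, or from embryos of 1 sex only, in the 6 arrays. The labels do not state whether embryos were pooled, and no explanation was tested further.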
